A study of Homo sapiens with 10 samples.

How the data were processed

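The series holds 10 samples of the NB4 cell line: 4 ChIP-seq libraries (PML/RARA, HDAC1, P300 and H3K27ac), 2 input libraries, and 4 RNA-seq libraries, with 2 of a vector control and 2 of sh-PML/RARA. Groups and replicate numbers were taken from the sample labels, and each of the 4 RNA columns matched 1 sample. Per the labels, the RNA libraries came from total RNA depleted of ribosomal RNA, after 6 hours of arsenic trioxide in every RNA library. The labels record no arsenic trioxide for the ChIP and input libraries. The input libraries have no processed values among the files, and which input served as control for which ChIP library is not given in the sources used here.

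Per the submitters' processing notes, ChIP reads were aligned with Bowtie2 2.2.9 to hg38 and peaks were called with MACS 1.4.2, giving 1 peak list per library. Per the file headers, each list gives the count of tags in each peak as a whole number. The fold enrichment over the caller's local background is a ratio named in the deposited lists, and the false discovery rate is given there in percent. The peak score, the negative decimal logarithm of the caller's p times 10, was deposited under a header cell that holds a spreadsheet error, so it was identified from its place and its values, which begin just above 100, the level of a p-value of 1e-10. The depth of the ChIP libraries is unknown, as the lists hold only peaks. Binomial intervals on shares of peaks therefore cover counting error alone.

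For RNA, the authors deposited a table of 35062 genes whose library columns hold FPKM, a unit not named in the header and inferred from column sums of 809000 to 833326 that differ between libraries. The submitters' notes name GRCh38 and DESeq2, while the comparison columns of the authors' deposited table carry edgeR's column names; the aligner, the counting tool and the annotation are not given in the sources used here. The authors' deposited table also holds their log2 fold change, their mean log2 CPM, and their p-value with its adjusted form, which equals the Benjamini-Hochberg value to within 2.4e-15. No read counts were analysed here, so the branch of the plan for normalized values was used. The relative depth, estimated from the most frequent ratio of values among genes above 0 in only the 2 libraries compared, and taken to be single fragments, was 1 and 0.957 in the vector libraries and 1.37 and 0.979 in the knockdown libraries. The floor of the authors' mean log2 CPM column, with a prior count of 2 assumed, corresponds to a mean depth of about 38.4 M fragments. Of the rows, 13090 were 0 in all libraries, and 15 symbols stood on 2 rows.

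Gene IDs were matched to the given gene name table (34977 of 35062) and to the RefSeq gene table of GRCh38 (29542 genes placed, 84.3%). The RefSeq table has no strand, so distances were measured to the nearer end of the gene span, which can be the 3' end, in place of the transcription start site. Chromosome length was taken as the largest coordinate in the tables used. Values were analysed as log2(FPKM + 1) for genes with at least 1 FPKM in 2 libraries (11971 genes). The groups were compared with limma 3.58.1 (trend, empirical Bayes) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The model had 2 residual degrees of freedom and a prior of 3.38. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333. Pearson correlations of log2 values were at least 0.986 within groups and at most 0.954 between groups.

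The 28 gene lists, the rule for named genes and the comparisons were fixed before the data were examined, and the literature list of PML/RARA targets was among them. Lists with at least 5 tested members were tested with camera (limma) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The second form rests on the 2 residual degrees of freedom of the model, so it has little power to call a list. Named genes were the 10 with the largest change in each direction among those past the threshold. They had a mean of at least 5 FPKM, libraries of one group all above the other, and a proper gene symbol. To these were added RARA and PML, up to 4 members per list with the lowest adjusted p, all members of the literature list, and the 5 bound genes with the largest change in each direction. Named peaks were the 5 PML/RARA peaks of highest fold and the highest at each named bound gene, and named joined regions were the 5 with the most tags. Some genes that this rule names are not reported here.

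Peaks were counted as overlapping from 1 bp. Expected overlaps came from 1000 circular shifts of all PML/RARA peaks along each chromosome, and, chosen after the data were seen, from 100 rounds of moving each peak by 20 to 200 kb. H3K27ac peaks at least 2.5 kb from a gene end were joined within 12.5 kb, ranked by tags, and divided where the scaled curve has a slope of 1. A gene was bound when a PML/RARA summit lay within 5 kb of either end. It was assigned to the P300 class if any such peak overlapped P300, to the HDAC1 class if any overlapped HDAC1 and none P300, and otherwise to neither. Shares were compared with two-sided Fisher's exact tests and classes by 100000 permutations of labels over genes. Sets were compared with 10000 random sets matched in 20 bins of mean expression. Peak work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

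The expression test was checked on simulated data for knockdown against vector, with 11688 genes, 200 of them changed, and 10 draws. It called 90.8% of genes changed by 1 on the log2 scale and 30.6% of those changed by 0.5; 9.43% of called genes were unchanged, and with no change simulated there were 0.8 calls per draw. A planted peak overlap of 30.0% was found as 30.0%. The alternatives tried were median scaling, pseudocounts of 0.1 and 0.01, other filters on low values, a replicate block, leaving out each RNA library in turn, and a minimum log2 change of 1. For peaks they were a cover of 50%, summits within 500 bp, peaks at or above the median score, windows of 1 and 50 kb, the nearest gene within 100 kb, and other joining rules. Motifs at PML/RARA peaks were left out because no genome sequence was at hand, and alternatives that need counts were left out because no counts were analysed here.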

Results

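Acute promyelocytic leukaemia carries a fusion of the genes PML and RARA, and NB4 is an established cell line from such a leukaemia that makes the fusion protein PML/RARA. Chromatin immunoprecipitation with sequencing (ChIP-seq) was used in NB4 cells to map PML/RARA, the deacetylase HDAC1, the acetyltransferase P300 and the acetylated histone mark H3K27ac. There was 1 library per antibody, so no peak value has a replicate error, and no values of the 2 input libraries were analysed here. RNA sequencing compared 2 libraries of NB4 cells carrying a control vector with 2 libraries of NB4 cells carrying a short hairpin RNA against PML/RARA (sh-PML/RARA, called the knockdown here). Per the labels, all 4 RNA libraries came from cells given arsenic trioxide for 6 hours, a drug that leads to degradation of PML/RARA. The lists held 6415 peaks for PML/RARA, 12330 for HDAC1, 4916 for P300 and 15808 for H3K27ac, with 652789, 640504, 295217 and 1202211 sequence tags inside the peaks. The FPKM of the RNA libraries (fragments per kilobase, scaled to library size) summed to between 809000 and 833326, and between 11603 and 11789 genes reached 1 FPKM in a library.

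The first comparison asked where on the genome PML/RARA lay together with HDAC1, P300 and H3K27ac. Of the 6415 PML/RARA peaks, 3122 (48.7%) overlapped an HDAC1 peak, 2488 (38.8%) a P300 peak and 2311 (36.0%) an H3K27ac peak. The peaks with the highest fold enrichment lay near GFOD1, near MIR223HG, the host gene of a myeloid microRNA, near LINC01600 and near NDRG1. PML/RARA peaks with P300 overlapped H3K27ac more often than those with HDAC1 and no P300, at 52.7% against 36.1%.

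The exact 95% binomial intervals of the overlaps, which cover counting error alone, were 47.4 to 49.9% for HDAC1, 37.6 to 40.0% for P300 and 34.8 to 37.2% for H3K27ac. When the PML/RARA peaks were shifted along their chromosomes 1000 times, the mean overlap was 0.463% with HDAC1, 0.177% with P300 and 0.755% with H3K27ac. In this permutation test none of the shifts reached the observed share, which gives p = 0.0010, the smallest that these shifts can give. Moving each peak by 20 to 200 kb, which keeps it in the same chromosomal neighbourhood, gave mean overlaps of 1.27% for HDAC1, 0.508% for P300 and 2.22% for H3K27ac. Seen from the other lists, 25.9% of the HDAC1 peaks, 51.0% of the P300 peaks and 16.3% of the H3K27ac peaks overlapped a PML/RARA peak. With only the HDAC1 or P300 peaks at or above the median score of their list, the shares of PML/RARA peaks with an overlap were 31.8% and 24.6%. In the H3K27ac list 15806 of the 15808 peaks had a false discovery rate above 5% in the authors' column (median 8.23%, highest 100%), while the highest value in the other lists was 4.55%.

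**Figure D1:**
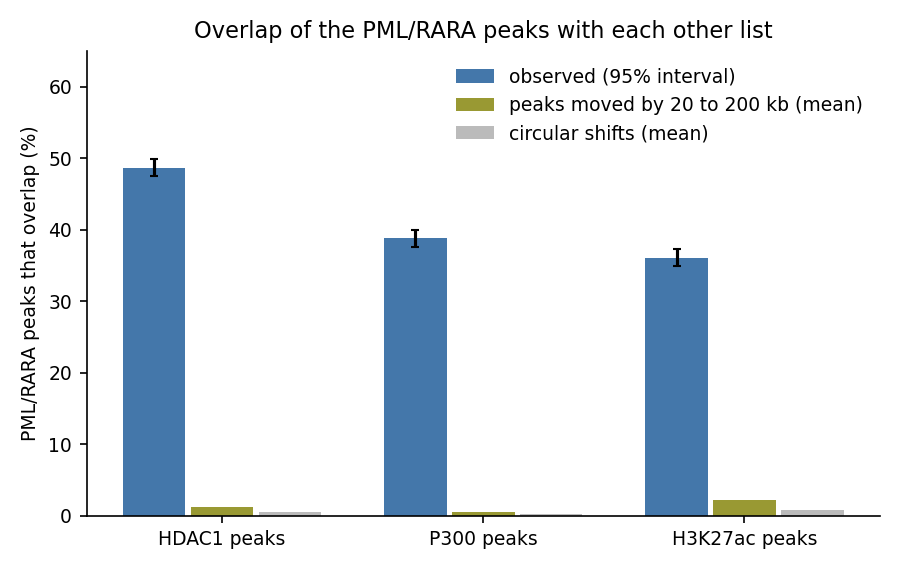
Share of the 6415 PML/RARA peaks (vertical axis, percent) that overlapped a peak of each other list, with exact 95% binomial intervals on the observed bars. The bars for moved and shifted peaks, each a mean, lie at or below 2.22%, against observed shares of 36.0 to 48.7%.

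By cofactor, 2017 PML/RARA peaks overlapped both P300 and HDAC1, 471 P300 without HDAC1, 1105 HDAC1 without P300, and 2822 neither. H3K27ac overlapped 54.0% of the peaks with P300 and HDAC1 (95% interval 51.8 to 56.2%) and 47.3% of those with P300 alone (42.8 to 52.0%). It overlapped 36.1% of those with HDAC1 and no P300 (33.3 to 39.0%) and 21.3% of those with neither (19.8 to 22.8%). For the peaks with P300 against those with HDAC1 and no P300 the odds ratio was 1.97 (95% interval 1.71 to 2.28, two-sided Fisher's exact test p = 2.9e-20). The odds ratio was 1.80 within 1 kb of a gene end and 2.42 farther away. PML/RARA peaks lay within 1 kb of an end of a protein-coding or long non-coding gene in 20.4% of cases (19.4 to 21.4%), against a mean of 5.08% for shifted peaks. The shares within 1 kb of a gene end were 41.6% for HDAC1, 13.3% for P300 and 41.8% for H3K27ac. Among PML/RARA peaks, 29.0% of those with HDAC1 and no P300 lay that close, and 15.1% of those with both P300 and HDAC1.

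On the GRCh38 build, the PML/RARA peak of highest fold enrichment in the authors' list (158) ran from 13407475 to 13408338 on chromosome 6, 50089 bp from the nearer end of GFOD1. Peaks at 65997811 to 65998752 and at 66011951 to 66012636 on chromosome X had folds of 131 and 128, with summits 17181 and 3190 bp from an end of MIR223HG. A peak at 2542537 to 2543522 on chromosome 6 had a fold of 128, with its summit 78879 bp from LINC01600. The peak at 133245562 to 133246450 on chromosome 8 had a fold of 126, with its summit 8951 bp from an end of NDRG1, a gene that responds to hypoxia and differentiation. All 5 overlapped P300, HDAC1 and H3K27ac peaks.

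H3K27ac peaks away from gene ends were joined into 3172 regions, and 112 of them held enough tags to form an upper class. A PML/RARA peak lay in 103 of these 112 regions (92.0%) and in 982 of the other 3060 (32.1%), an odds ratio of 24.2 (95% interval 12.2 to 48.1, two-sided Fisher's exact test p = 6.5e-39). With single H3K27ac peaks in place of joined regions the odds ratio was 7.31. The upper regions were longer, with a median of 23.1 kb against 1.12 kb, and per 100 kb they held 9.76 PML/RARA summits against 11.5 in the other regions. That direction turned with single peaks in place of joined regions (22.8 against 13.2) and with peaks near a gene end kept (9.88 against 7.71). Distances given for single regions run from the middle of the region to the nearer gene end, so a region can reach closer or lie inside the gene. The region with the most tags, 8514, ran from 129535074 to 129596906 on chromosome 8, 139 kb from an end of GSDMC. The second, with 7311 tags, ran from 371059 to 430326 on chromosome 5, 37.6 kb from an end of AHRR. The next lay at 129629855 to 129696477 on chromosome 8 near GSDMC, at 127799116 to 127837397 on chromosome 8, 75.3 kb from MYC, and at 77051623 to 77131660 on chromosome 18, 42.1 kb from an end of MBP, the gene of myelin basic protein. They held 9, 4, 4, 2 and 7 PML/RARA summits in that order.

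The genes that form the fusion carried a set of tall peaks, chosen for description after their values were seen. Within RARA, which runs from 40309180 to 40357643 on chromosome 17, the HDAC1 list held 7 peaks with folds of 103 to 140, all between 40348295 and 40356242. Each overlapped a P300 peak, with folds of 54.6 to 72.9, and none overlapped an H3K27ac peak or a PML/RARA peak. Within PML, from 73994716 to 74047827 on chromosome 15, HDAC1 peaks with folds of 63.8, 68.1 and 129 also overlapped P300 peaks and no H3K27ac peak. Of the 10 HDAC1 peaks with a fold of at least 100 in the whole list, 8 lay in RARA or PML. The PML/RARA list had peaks of folds 26.6 and 40.8 in PML that coincided with the HDAC1 and P300 peaks there, and peaks of folds 9.01 to 15.8 in RARA.

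**Figure D2:**
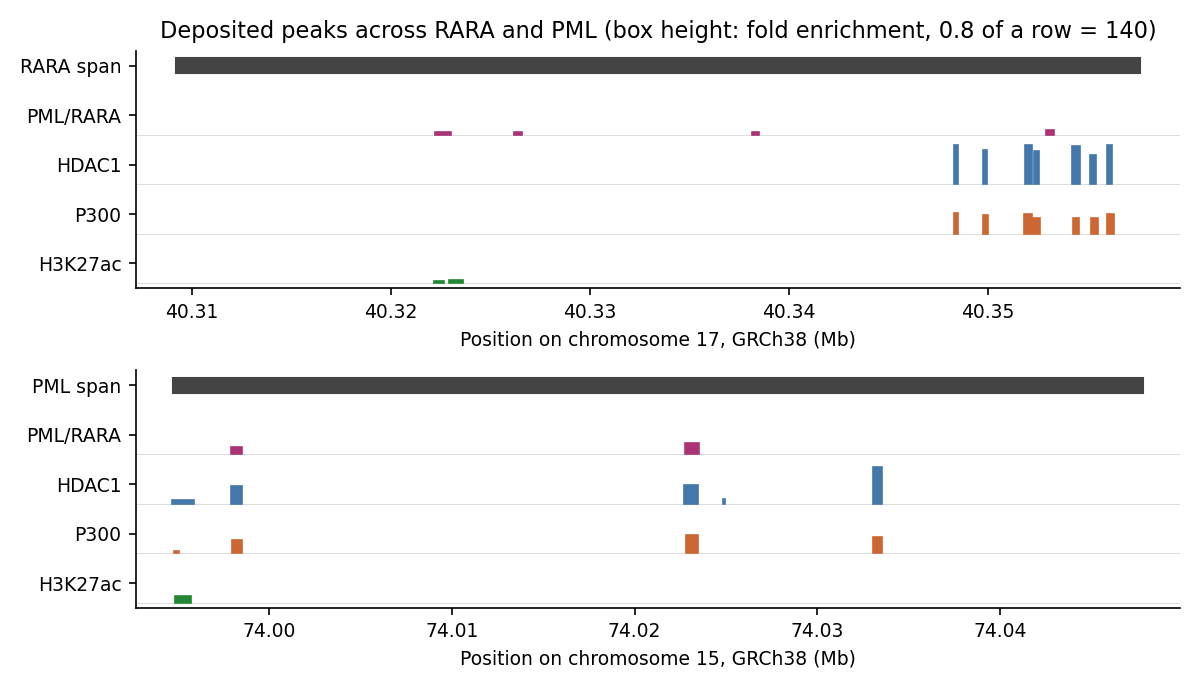
Peaks of the 4 lists across RARA and PML (horizontal axis, position in Mb on GRCh38); box width is the peak and box height its fold enrichment, drawn so that a fold of 140 fills 0.8 of a line. HDAC1 and P300 boxes coincide at 7 places in RARA and at 3 tall places in PML, where H3K27ac has no box.

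The second comparison asked which transcripts differ when PML/RARA is knocked down. The genes of the fusion were examined first. The fusion transcript has no value of its own, and its reads count towards both RARA and PML. RARA stood at 20.3 and 22.1 FPKM in the vector libraries and at 13.4 and 12.6 in the knockdown libraries. It fell by 0.67 on the log2(FPKM + 1) scale (SE 0.11, n = 2 and 2, limma adjusted p = 0.0088). PML was at 36.5 and 37.3 FPKM in the vector libraries and at 39.6 and 38.7 in the knockdown libraries, and so did not fall (log2 change 0.08, limma adjusted p = 0.452). These values do not show whether, or by how much, the fusion transcript itself changed. Without knockdown replicate 2, the adjusted p of RARA was 0.0555.

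Genes that answer metals and oxidants were among those that rose most after knockdown, and genes of sterol synthesis and inflammatory signalling were among those that fell most. HMOX1, which degrades haem, went from 1.42 ± 0.26 FPKM (SD, n = 2) with the vector to 1292 ± 109 with the knockdown. MT2A, a metallothionein that binds zinc and copper, went from 808 ± 25.7 to 23394 ± 1852, and INSIG1, which restrains sterol synthesis, from 465 ± 174 to 42.8 ± 10.8. MYC fell from 419 ± 49.0 to 134 ± 6.64, and the granule enzyme MPO from 1954 ± 54.4 to 1001 ± 35.9. In all, limma with Benjamini-Hochberg adjustment called 2627 of 11971 genes higher and 2261 lower at an adjusted p below 0.05, and 637 and 479 of these changed by at least 1 on the log2 scale.

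All log2 changes given for genes are knockdown minus vector on the log2(FPKM + 1) scale, which understates the change of genes with low values. Nothing says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. An arsenic exposure that differed between the groups would enter each of these changes, and the labels are the only record of it. For every gene said to have risen or fallen, both knockdown libraries lay on the same side of both vector libraries. The counts fell to 1310 higher and 1392 lower without knockdown replicate 1, to 1195 and 1290 without knockdown replicate 2, and to 1745 and 1449 with no filter on low values.

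The 10 largest rises by the fixed rule were those of HMOX1, MT1X, MT1F, MT2A, OSGIN1, CLU, STOX2, SULT1A4, HTRA3 and FRG1. HMOX1 rose by 9.06 (SE 0.11, limma adjusted p = 1.1e-05), MT1X by 5.86, MT1F by 5.11 and MT2A by 4.85 (SE 0.07 to 0.12). OSGIN1, induced by oxidative stress, rose by 3.99 and CLU, the secreted chaperone clusterin, by 3.90, from 18.6 ± 3.42 to 289 ± 8.17 FPKM. STOX2 rose by 3.72, and HTRA3, a secreted serine protease, by 3.56, from 25.1 ± 1.90 to 307 ± 0.31 FPKM. SULT1A4, a sulfotransferase, rose by 3.69. FRG1 was listed at 0 in both vector libraries and at 6.79 and 13.3 FPKM in the knockdown libraries. SULT1A4, FRG1 and the MT1 genes have near-identical copies in the genome, so their values are uncertain.

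The largest falls were those of INSIG1, TNFAIP3, CD300A, SCD, HILPDA, CD70, LGALS12, SH3D19, SLC2A3 and TP53I11. INSIG1 fell by 3.38 (SE 0.29, limma adjusted p = 0.0024) and TNFAIP3, a brake on NF-kappaB signalling, by 2.82, from 19.2 ± 3.48 to 1.85 ± 0.40 FPKM. SCD, a fatty acid desaturase, fell by 2.41, and CD70, a ligand of the tumour necrosis factor family, fell by 2.39. LGALS12, a galectin, fell by 2.32, SH3D19 fell by 2.21 and TP53I11 fell by 2.17. The inhibitory myeloid receptor CD300A fell by 2.64, the lipid droplet gene HILPDA fell by 2.39 and the glucose transporter SLC2A3 fell by 2.21. The vector libraries differed for these last genes, at 17.2 and 5.43 FPKM for CD300A, 78.2 and 25.1 for HILPDA, and 242 and 88.5 for SLC2A3. With no filter on low values their adjusted p was 0.0648, 0.0817 and 0.0780, and without vector replicate 1 HILPDA changed by -1.59.

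**Figure D3:**
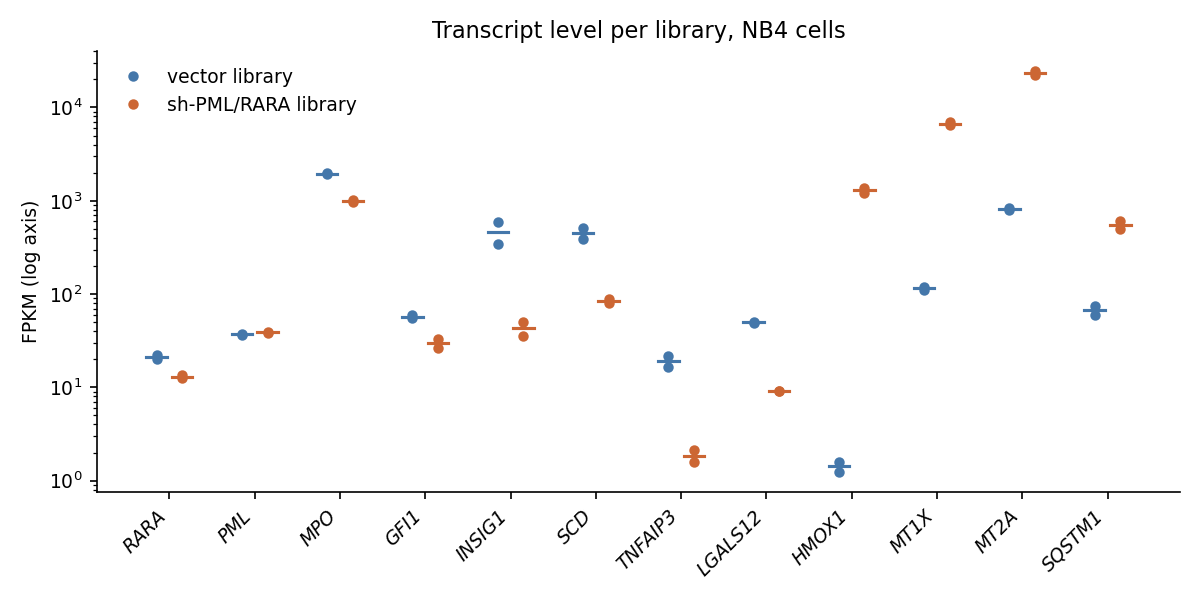
FPKM of 12 genes (log axis) in each vector library and each sh-PML/RARA library; points are libraries and bars are means of the 2 libraries of a group. The groups are well apart for most genes shown and close together for PML, which was not called, and HMOX1 runs from about 1 FPKM to above 1000.

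Of the gene lists fixed in advance, 3 rose as sets. In the NRF2 oxidative stress list 19 of 23 tested members rose and none fell (20 adjusted over the list alone), among them SQSTM1, the autophagy receptor, by 3.01 and NQO1, a quinone reductase, by 1.34. All 5 tested members of the metallothionein list rose (5 adjusted over the list alone), including the zinc exporter SLC30A1 by 1.5. In the heat shock list 14 of 18 rose and 1 fell (15 and 3 adjusted over the list alone). HSPH1 rose by 1.80, DNAJB1 by 1.68, HSPA8 by 1.43 and HSP90AA1, the inducible cytosolic chaperone, by 1.4. The camera test of limma with a preset correlation gave adjusted p = 1.4e-09 for NRF2 (mean log2 change 1.70) and 2.7e-05 for metallothioneins (3.82) and for heat shock (0.85). Each had an adjusted p = 0.460 with an estimated correlation, and so lost the call. The estimated correlations were -0.045 for NRF2, 0.002 for metallothioneins and 0.086 for heat shock, against the preset 0.01. For NRF2 and metallothioneins a higher correlation is thus not what ended the call. That form of the test rests on 2 residual degrees of freedom. Metallothionein genes, HMOX1 and heat shock genes are known to be induced by arsenic compounds, and the labels give all 4 libraries the same arsenic exposure. Yet HMOX1 stood at only 1.24 and 1.60 FPKM in the vector libraries, so whether the exposure was equal stays open.

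Cholesterol synthesis and NF-kappaB cytokine genes fell as sets in the camera test with the preset correlation of 0.01. For the cholesterol list the correlation was estimated at 0.412, so correlated members may have strengthened its call. In the cholesterol list 17 of 23 fell and none rose (19 adjusted over the list alone). DHCR7, which makes cholesterol from its last precursor, fell by 1.77, FDFT1, squalene synthase, by 1.21 and EBP by 1.03 (list mean -1.03, camera adjusted p = 1.0e-08; adjusted p = 0.478 with an estimated correlation). In the cytokine list 10 of 14 fell and none rose (10 adjusted over the list alone), among them CCL5 by 0.96, RELB by 1.37 and ICAM1 by 1.08 (list mean -0.99, camera adjusted p = 7.3e-05; adjusted p = 0.460 with an estimated correlation). In the glycolysis and hypoxia list 10 of 23 fell and 4 rose (11 and 5 adjusted over the list alone), with LDHA lower by 0.91, PGAM1 by 0.77, ADM by 1.28 and PFKP by 0.47. That list was not called (camera adjusted p = 0.131). It was called without vector replicate 2 (adjusted p = 0.00479), without knockdown replicate 1 (0.0101) and without knockdown replicate 2 (0.0027). PFKP had adjusted p = 0.0534 without knockdown replicate 1.

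Among myeloid genes, the primary granule list fell, with 8 of 17 lower and 2 higher (9 and 2 adjusted over the list alone; list mean -0.43, camera adjusted p = 0.0113, or adjusted p = 0.460 with an estimated correlation). With a library left out the list mean ran from -0.66 (without knockdown replicate 1) to -0.29 (without vector replicate 1). MPO fell by 0.97, RNASE2 by 0.79, SRGN, the granule proteoglycan, by 1.03 and CALR by 0.99. The list of myeloid transcription factors fell too, with 13 of 30 lower and 3 higher (13 and 3 adjusted over the list alone; list mean -0.31, camera adjusted p = 0.00688, or adjusted p = 0.478 with an estimated correlation). MYB fell by 1.04, ETS1 by 1.24, STAT5B by 0.87 and KLF13 by 0.76. Late granulocyte genes went both ways, with 6 of 13 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.290). S100P rose by 1.4 and CEBPE, a granulocyte transcription factor, by 1.13, and MMP9 fell by 1.85. Of the monocyte and macrophage genes 6 of 11 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.131), with FCGR1A at -1.44, IRF8 at -1.48, KLF4 at -0.89 and CD68 at -0.71, where KLF4 had adjusted p = 0.0602 without knockdown replicate 2. Of the stem and progenitor genes 3 of 10 fell and none rose (3 adjusted over the list alone, camera adjusted p = 0.266), namely MYB, HMGA2 by 1.04 and GATA2 by 0.59.

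Markers of other cell types moved as well. The T and NK cell list fell, with 5 of 6 tested members lower and none higher (5 lower and 1 higher adjusted over the list alone). CD4, which myeloid cells also carry, fell by 0.96, CD3D by 1.55, NKG7 by 0.84 and TRAC by 0.68 (list mean -0.73, camera adjusted p = 0.0116; adjusted p = 0.460 with an estimated correlation). In the B and plasma cell list 1 of 4 tested members was called, CD79B, which fell by 1.92. The log2 change was -0.35 for CD79A, which was not called (1 lower adjusted over the list alone). None of the 3 tested erythroid and megakaryocyte markers (ITGA2B, EPOR and GATA1) and none of the 3 epithelial and fibroblast markers (EPCAM, ACTA2 and KRT8) was called, over all genes or adjusted over the list alone. Without knockdown replicate 1, ITGA2B was called (-1.11, adjusted p = 0.0148), against -0.79 with all libraries, and the erythroid list had a mean of -0.15 and a median of 0.14. These last 3 lists had too few tested members for camera. The mitochondrially encoded genes held 3.32% and 3.72% of the FPKM in the vector libraries and 3.01% and 2.63% in the knockdown libraries.

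The MYC and ribosome biogenesis list fell, with 12 of 28 lower and 2 higher (12 and 2 adjusted over the list alone). Its correlation was estimated at 0.574, far above the preset 0.01, so correlated members may have made its camera call. MYC fell by 1.64, CAD, the enzyme that starts pyrimidine synthesis, by 0.70 and NOLC1 by 0.69 (list mean -0.26, camera adjusted p = 0.00738; adjusted p = 0.670 with an estimated correlation). Without vector replicate 2 the list mean was -0.12 and the adjusted p 0.180, and without vector replicate 1 the mean was -0.41. Cell cycle genes split, with 6 of 34 higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.950). RRM2, a subunit of ribonucleotide reductase, rose by 1.23, CCNE2 by 1.55 and CENPE by 0.99, and the helicase subunit MCM7 fell by 1.75. Replication histone genes had 3 of 5 lower (3 adjusted over the list alone, camera adjusted p = 0.110), HIST1H1C by 0.80, HIST1H2AC by 0.84 and HIST1H2BC by 0.90, with HIST1H2BD at -0.56. Leaving out a library ended these calls for HIST1H1C (adjusted p = 0.0880 without knockdown replicate 1), HIST1H2AC (0.120 without knockdown replicate 1, 0.0734 without 2) and HIST1H2BC (0.107 without vector replicate 1, 0.155 without knockdown replicate 2). HIST1H2BD was called without vector replicate 2 (-1.02, adjusted p = 0.0143).

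Genes reported in the literature as PML/RARA targets went both ways, with 6 of 23 higher and 9 lower (6 and 9 adjusted over the list alone; camera adjusted p = 0.302). TNFAIP2 rose by 1.79, ID2 by 1.61, PRAM1 by 1.24, ID1 by 1.13, CEBPE by 1.13 and IRF1 by 0.90. FOS fell by 1.51, IRF8 fell by 1.48, JUP by 1.06, GFI1, a repressor in granulocyte development, by 0.92, CD44 by 0.90, DUSP6 by 0.78, PTPN6 by 0.77, CCL2 by 0.70 and GATA2 by 0.59. Without vector replicate 1 the changes were -0.94 for FOS, -0.45 for DUSP6 and -0.57 for CD44. The calls of CCL2 and CD44 were lost when single libraries were left out. CCL2 had adjusted p = 0.0536 without vector replicate 2, 0.111 without knockdown replicate 1 and 0.162 without knockdown replicate 2, and CD44 had 0.0530 without vector replicate 1 and 0.0695 without knockdown replicate 2. With no filter on low values the calls of ID1, IRF1, CCL2, FOS, CD44 and DUSP6 were lost, at adjusted p from 0.0575 for ID1 to 0.135 for DUSP6. The master regulators SPI1, CEBPA and RUNX1 were not called, at -0.22, -0.15 and -0.19, nor were NFE2 (-0.32), CEBPB (1.08), SYK (-0.19) and CDKN1A (0.12). Without vector replicate 1 the calls of SPI1 (-0.40, adjusted p = 0.0315), CEBPA (-0.56, 0.021) and SYK (-0.42, 0.0139) were made. CEBPB was called without vector replicate 2 (1.78, adjusted p = 0.0112) and without knockdown replicate 1 (1.35, 0.0121). Without vector replicate 2, CEBPA and SYK stood at 0.27 and 0.04, not called.

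The other lists were not called as sets. Of the retinoic acid response genes 7 of 12 fell and 2 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.110), with CRABP2 lower by 1.90, CD38 lower by 1.66, and TNFAIP2 higher by 1.79. RARA itself is among the 7, and its reads include those of the fusion transcript, the target of the hairpin. The interferon list had 5 of 27 higher and 4 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.689), with IFIT3 higher by 1.43, OAS1 by 1.24 and HERC5 by 0.98, and CXCL10 lower by 2.41. Unfolded protein response genes had 9 of 21 higher and 7 lower (9 and 7 adjusted over the list alone, camera adjusted p = 0.902). PHGDH, of serine synthesis, rose by 1.38, and the endoplasmic reticulum proteins PDIA4 and SDF2L1 fell by 1.41 and 1.24. In the p53 list 6 of 21 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.477), with GADD45A higher by 1.49, PMAIP1 by 1.17 and SESN2 by 0.89, and TNFRSF10B lower by 1.09.

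For apoptosis genes the counts were 7 of 23 higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.950), with a list mean of 0.02 (-0.02 with median scaling) against a median of -0.06. FADD, an adaptor of death receptors, rose by 0.69. Coagulation and fibrinolysis genes had 3 of 10 higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.795). ANXA2, a cell surface receptor in fibrinolysis, rose by 1.37 and TBXAS1 by 0.81, and the urokinase receptor PLAUR and urokinase PLAU fell by 1.32 and 1.29 (adjusted p = 0.0507 for PLAU with no filter on low values). In the immediate early list 6 of 20 fell and 3 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.242), NR4A1 by 1.32, DUSP2 by 1.06 and JUNB by 0.91 among the falls and FOSL1 by 0.81 among the rises. Without vector replicate 2 that list was called (adjusted p = 0.0206). Chromatin cofactors had 8 of 28 higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.444), with NCOA1 higher by 1.25, NCOA2 by 1.03 and HDAC1 itself by 0.50, and DNMT1 lower by 0.49. Of the PML body genes 6 of 19 rose and none fell (6 adjusted over the list alone, camera adjusted p = 0.182), including HIPK2 by 0.62. HIPK2 lost its call with no filter on low values (adjusted p = 0.0580), without knockdown replicate 1 (0.109) and without knockdown replicate 2 (0.122).

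**Figure D4:**
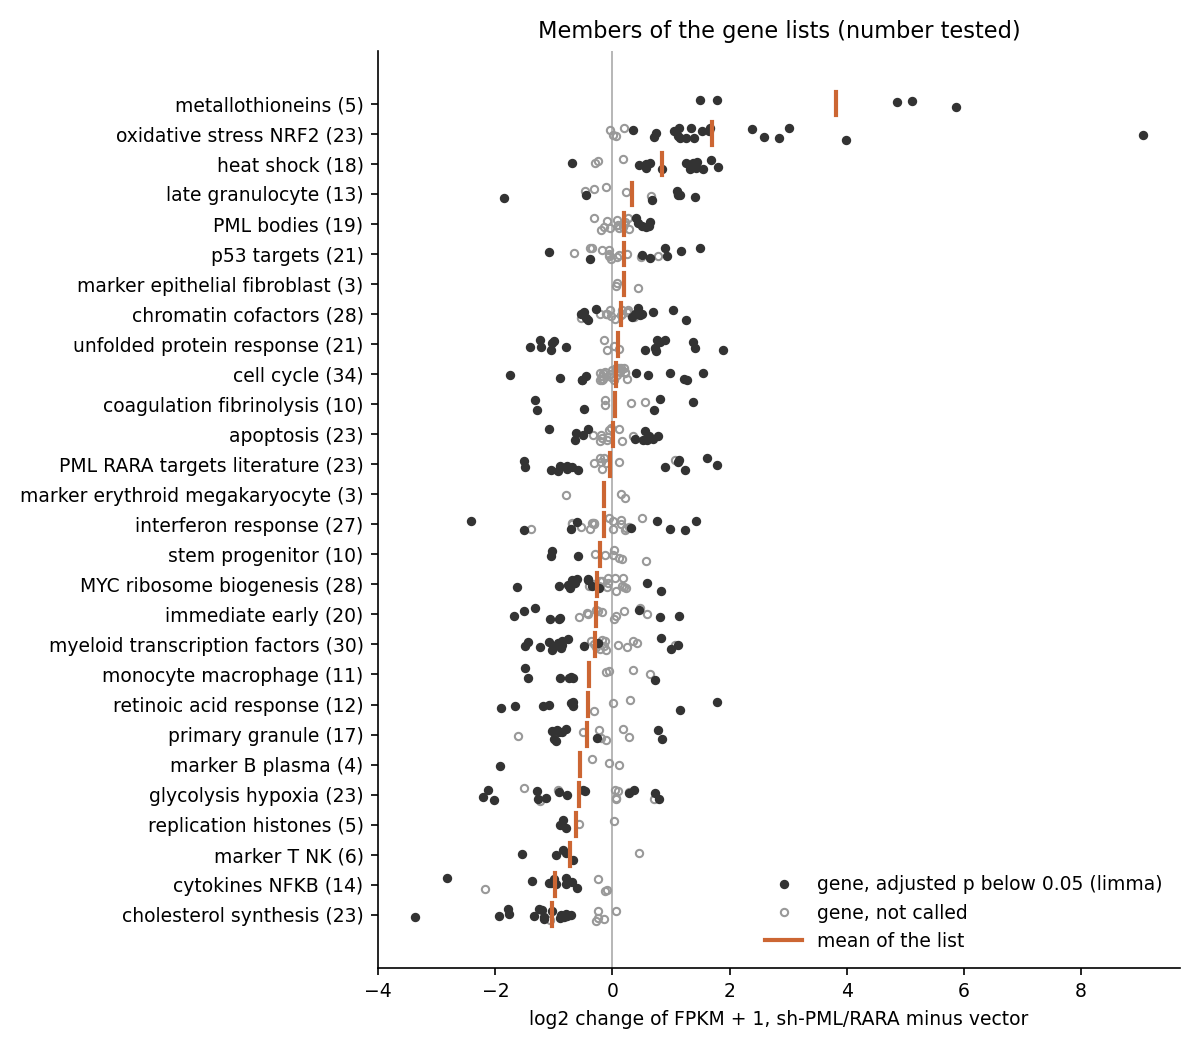
Log2 change of FPKM + 1, knockdown minus vector (horizontal axis), of the tested members of the 28 gene lists, with the number tested in brackets; filled points are genes called by limma and upright bars are list means. The metallothionein, NRF2 and heat shock lists have means of 3.82, 1.70 and 0.85, and the cholesterol list has a mean of -1.03.

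The authors' deposited table, which holds the authors' own comparison, lists 3062 genes higher and 3057 lower at an adjusted p below 0.05. Of the 4888 genes called here by limma, 4164 (85.2%) are called in the same direction in the authors' deposited table. The authors' deposited table gives a log2 fold change of -0.72 for RARA, 0.01 for PML, 10.01 for HMOX1 and -1.02 for MPO.

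The third comparison joined binding to expression and asked whether genes with a PML/RARA peak near either end changed with the knockdown. The labels record arsenic for the RNA libraries and none for the ChIP libraries. The peaks therefore may not show where PML/RARA lay in the cells used for RNA. Genes with a PML/RARA peak near an end were called lower more often than other genes, and called higher about as often. Genes with a P300 peak and no PML/RARA peak were also called lower more often than genes with neither. Among bound genes, CD300A, LGALS12, TP53I11, HK2 and CTDSP1 fell most and HMOX1, MT2A, SQSTM1, SLC16A6 and SLC48A1 rose most. Bound genes whose peaks included P300 lay lower after knockdown than bound genes with HDAC1 and no P300.

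Of the 11548 tested genes with a position, 1611 had a PML/RARA summit within 5 kb of a gene end. Of these 419 (26%) were lower, against 17.9% of the unbound genes (odds ratio 1.61, 95% interval 1.42 to 1.82, two-sided Fisher's exact test p = 1.2e-13). With the background matched on mean expression the pooled odds ratio was 1.55 (95% interval 1.37 to 1.75). Genes with P300 within 5 kb and no PML/RARA had a like share, with 27.4% of 303 lower and 15.8% higher. For PML/RARA without P300 (1087 genes) the shares were 22.3% and 24.2%, for both (524 genes) 33.8% and 18.1%, and for neither 17.6% and 22.3%. A raised share of lower genes was thus not confined to genes with PML/RARA. The share was also higher with PML/RARA than without it, at 33.8% against 27.4% with P300 and at 22.3% against 17.6% without P300. These differences in share were not tested. For genes called higher the share was 22.2% among bound genes and 22.1% among unbound genes (odds ratio 1.0, 95% interval 0.886 to 1.14, Fisher's exact test p = 0.948). By the same exact test, that odds ratio turned to 0.889 (p = 0.0105) with a window of 50 kb and was 1.25 (p = 0.00948) without knockdown replicate 2. As a set, the bound genes had a median log2 change of -0.04, below all 10000 random sets of like expression (95% of them between 0.00 and 0.05). It was -0.01 without vector replicate 1, and with a window of 1 kb or with the PML/RARA peaks at or above the median score it lay at percentiles 2 and 1.75 of such sets. The camera test of limma gave p = 0.171 for the set (n = 1611 genes). Genes are not independent replicates, which limits each of these tests.

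The bound genes with P300 (490) had a mean log2 change of -0.15 ± 0.76 (SD), and those with HDAC1 and no P300 (427) had 0.05 ± 0.66. The difference of -0.19 (SE 0.05) had a two-sided permutation p = 5.0e-05. By the same permutation test it was -0.10 (p = 6.0e-05) with a window of 50 kb and -0.14 (p = 0.0342) with a window of 1 kb. Without vector replicate 1 the difference was -0.15. In the P300 class 166 genes were lower and 90 higher, in the HDAC1 class 96 and 117, and in the class with neither 157 and 151 of 694. The camera test called the P300 class (adjusted p = 0.00657), but not with the correlation estimated (adjusted p = 0.238 with an estimated correlation), and called neither other class (adjusted p = 0.83 and 0.725). The correlation estimated for the P300 class was 0.008, below the preset 0.01, so a higher correlation is not what ended its call.

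**Figure D5:**
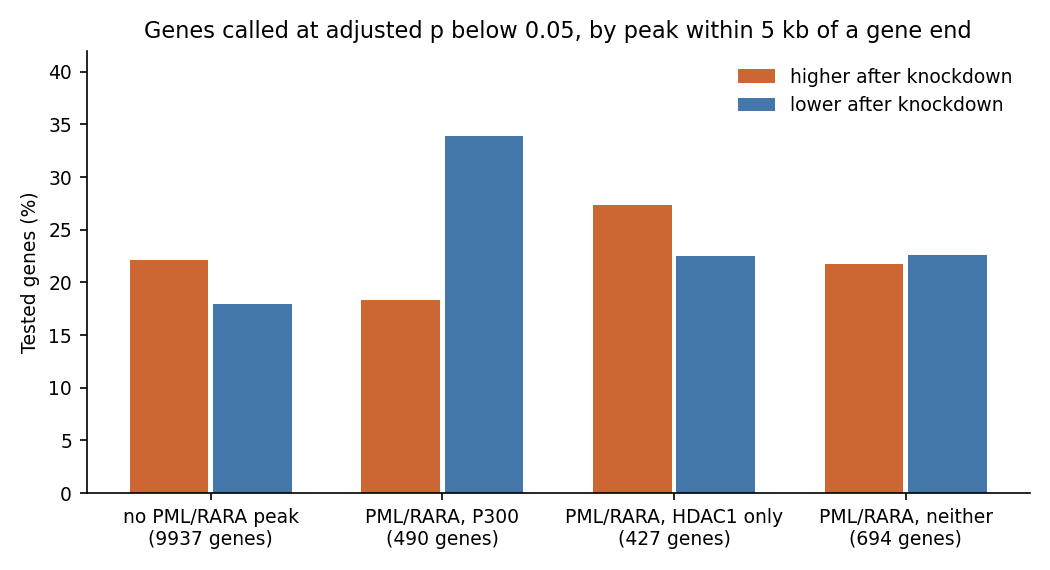
Percent of tested genes called higher or lower after knockdown (vertical axis) for genes with no PML/RARA peak within 5 kb of a gene end and for bound genes by cofactor class. In the P300 class 33.9% of genes were lower and 18.4% higher, and in the HDAC1 class 22.5% and 27.4%.

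Over the whole PML/RARA list the median fold was 17.8, with quartiles of 13.1 and 25.3. Among the bound genes that fell, CD300A had a PML/RARA peak of fold 34.8 at 74463309 to 74463920 on chromosome 17. LGALS12 had a peak of fold 14.8 at 63503487 to 63503793 on chromosome 11, and TP53I11 a peak of fold 17.3 at 44955120 to 44955465 on the same chromosome. Each of these lay outside the gene span and overlapped P300 and HDAC1 peaks. The peak of HK2, which codes for a hexokinase, had a fold of 15.4 and was at 74832060 to 74832493 on chromosome 2, outside its span and with neither cofactor. CTDSP1, a phosphatase gene, had 4 peaks, the strongest of fold 11.7 at 218397957 to 218398436 on chromosome 2 inside its span. Of these genes only CD300A had a peak above the median fold of the list. HK2 fell by 2.12 from 137 and 59.4 FPKM in the vector libraries (adjusted p = 0.0592 with no filter on low values), and CTDSP1 fell by 2.11.

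Among the bound genes that rose, the HMOX1 peak lay at 35376925 to 35377329 on chromosome 22 with a fold of 11.5, and the MT2A peak at 56610068 to 56610606 on chromosome 16 with a fold of 9.11. Both folds lay below the lower quartile of the list, 13.1. Neither peak overlapped a P300 or HDAC1 peak. The SQSTM1 peak, at 179803572 to 179804508 on chromosome 5, had a fold of 34 and overlapped both. SLC16A6, a transporter that rose by 2.65, and SLC48A1, a haem transporter that rose by 2.49, had peaks of folds 13.4 and 11.7. MPO and CEBPE, which moved in opposite directions, had 3 and 4 PML/RARA peaks, with highest folds of 24.2 and 46.6, and GFI1 had 3 with a highest fold of 44.4.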

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

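The peak displacement by 20 to 200 kb, the rule that counts a peak inside a gene, the estimated correlation for bound genes and the split by distance to a gene end were tests chosen only after the results were seen. Over the main results, 241 alternative values kept their side of the threshold (or stayed within 1.5 times for counts of genes, and within the binomial interval for shares of peaks), 19 moved, 5 passed the threshold, 12 lost it and 1 reversed. In 13 of the 241 the direction turned with no call in either setting, for the cell cycle, interferon, coagulation and apoptosis lists and for bound genes among those higher. For lists this is the direction that camera gives, which can turn while the list mean keeps its sign. The interferon list turned in both, with a mean that went from -0.15 to 0.14 without vector replicate 1. Over the named genes, 1396 of 1486 alternative values were unchanged in call, 79 lost it (41 of them under the minimum log2 change of 1), 11 gained it and 0 reversed, while 11 turned direction with no call in either setting. The causes were not tested, except that leaving out libraries means fewer samples and no filter means more genes tested. Where a group was left with 1 library, limma assumes that it varies like the other group.

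Genes higher and lower numbered 1745 and 1449 with no filter, 637 and 479 with a log2 change of at least 1, and 1195 to 3163 and 1290 to 2613 with a library left out. A block on replicate number gave 2817 and 2499, but deviations of libraries with the same number correlated at only 0.0629 over 9115 genes, so the numbers are not shown to pair the libraries. That block also called CEBPB (1.08, adjusted p = 0.0047) and ITGA2B (-0.79, adjusted p = 0.0156). With an estimated correlation the adjusted p was 0.460 for the primary granule, NRF2, metallothionein, heat shock, cytokine and T and NK lists, 0.478 for the cholesterol and myeloid transcription factor lists and 0.670 for the MYC list. The correlation was estimated at 0.412 for the cholesterol list and 0.574 for the MYC list, but at -0.045 for NRF2. That test rests on 2 residual degrees of freedom, so where the estimate lay near or below 0.01 a lost call does not show that correlated genes had made it. For the MYC and cholesterol lists the high estimates mean that correlated genes may have made or strengthened the call. Before adjustment over the lists, camera with the estimated correlation gave p = 0.482 for MYC and p = 0.166 for cholesterol. With a library left out the adjusted p ran from 1.5e-05 to 0.180 for MYC, from 0.0206 to 0.580 for immediate early genes and from 0.0027 to 0.151 for glycolysis. The change of RARA ran from -0.73 to -0.61 with a library left out, and at -0.67 it misses a minimum log2 change of 1 by construction. The odds ratio of bound genes among those higher reversed to 0.889 at 50 kb and ran from 0.955 to 1.25 with a library left out, against 1.0.

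The overlaps of PML/RARA peaks with HDAC1, P300 and H3K27ac were 42.3%, 34.7% and 24.8% with 50% of the peak covered. They were 57.8%, 49.9% and 41.8% for PML/RARA peaks at or above the median score, and 31.8%, 24.6% and 26.4% against the other list's peaks at or above its median. For H3K27ac, 27.3% had summits within 500 bp. With protein-coding genes alone, 14.2% of PML/RARA peaks lay within 1 kb of a gene end. Not run were DESeq2 and library-size alternatives, which need counts, and motifs, which need a genome. The unknown ChIP depth limits what the absence of a peak can show.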

Other observations

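The tests of arsenic exposure, of a few genes taking the FPKM, of DNA copies and of acetylated elements, the expression-matched check of bound stress genes and the fold limits for the RARA and PML peaks were chosen only after the results were seen. PML/RARA peaks within 5 kb of a gene end were not found for CEBPA, CEBPB, IRF8, GATA2, MYB, ETS1 or STAT5B. NFE2 had 4 (highest fold 67.4), SPI1 3 (58.0), RUNX1 2 (56.9) and PRAM1 5 (27.5), while ID1 and CCL2 had 1 each, with folds of 77.5 and 80.0. The peaks of NFE2 and PRAM1 with the highest fold overlapped P300 and HDAC1, those of SPI1 and RUNX1 P300 without HDAC1, that of CCL2 HDAC1 without P300, and that of ID1 neither. Among genes that fell, CD38 had a peak of fold 42, DUSP6 of 36.7, CALR of 35.6 and FCGR1A of 31.1.

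Of 46 tested metallothionein, NRF2 and heat shock genes, 38 were called higher after knockdown and HSPB1 lower. All 3 lists lost their camera call with an estimated correlation (adjusted p = 0.460), a test that rests on 2 residual degrees of freedom. A few genes taking most of the FPKM is argued against: the 10 genes with the most held more in the knockdown libraries, which shifts all other genes by -0.039 on the log2 scale, against a mean change of 1.60 for these 46 (SD 1.77). Unequal arsenic exposure cannot be told apart from the knockdown. HMOX1, which arsenic induces, had a mean of only 1.42 FPKM in the vector libraries although the labels give them arsenic. No RNA library lacks arsenic per its label, which bears on every change between the groups. Direct repression by PML/RARA is a candidate explanation for part of the set: 34.2% of the members called higher (13 of 38) had a PML/RARA peak, against 13.9% of other genes (two-sided Fisher's exact test p = 0.0013), and 36 of 10000 expression-matched sets had as many. The 3 lists were taken up for this test because they rose. Over all tested genes with a position, 22.2% of bound genes and 22.1% of unbound genes were called higher. The PML/RARA peaks come from ChIP libraries with no arsenic in their labels, so they may not show binding in the cells used for RNA. Among the 13 were FTL, HMOX1, GSR, MT2A, DNAJB1, BAG3, SQSTM1, FTH1 and NQO1. Of the 13, 5 were in the HDAC1 class, 2 in the P300 class and the rest in neither. The peaks of HMOX1, MT2A and NQO1, with folds of 11.5, 9.11 and 12.7, lay below the lower quartile of the PML/RARA list (13.1). Those of SQSTM1 and DNAJB1, with folds of 34 and 23.8, lay above its median (17.8).

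RARA and PML held 10 tall HDAC1 peaks that coincided with P300 peaks. Of the 10, 0 overlapped H3K27ac, against 12 of 24 other such peaks (50%, two-sided Fisher's exact test p = 0.0058), but the 10 were chosen after this was seen and 7 lie in RARA, so acetylated regulatory elements stay open. DNA copies of the fusion transcript in the HDAC1 and P300 libraries stay open too: 0 other genes held 3 or more such peaks, but the fold limits were set after these peaks were seen and there were 24 others, so that count decides nothing. The gene table has no exons, so whether the peaks sit on exons was not tested, and no biological explanation beyond acetylated elements was tested. PML/RARA peaks overlapped 2 of the 10, against 17 of the 24 others.

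Bound genes with P300 were lower after knockdown than bound genes with HDAC1 and no P300. A difference in expression level as the whole cause is argued against, since the difference was -0.20 within 10 bins of mean expression (permutation p = 0.0001, the smallest that 10000 permutations can give). P300 at a gene, with or without PML/RARA, may account for it: the 303 genes with P300 and no PML/RARA lay lower than genes with neither by a difference of -0.18 (permutation p = 0.0001, again the smallest possible). Genes with P300 and PML/RARA differed from those with P300 alone by -0.04 (permutation p = 0.478), which does not show that they are alike. A role of PML/RARA itself at these genes stays open, as does unequal arsenic exposure.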
